A study of Homo sapiens with 21 samples.

How the data were processed

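RUNX1 binding was measured by chromatin immunoprecipitation and sequencing in Jurkat, an established human T-cell leukaemia line, in clones whose RUNX1 alleles carry short epitope tags. Per the labels' protocols, cells were fixed for 15 min, the fixation was stopped for 5 min, chromatin was sonicated and precipitated with a high-sensitivity kit and anti-HA or anti-TY1 antibody, and libraries were sequenced on a NovaSeq instrument. In the mutant clones HA marked the mutant protein and TY1 the wild-type protein, whereas in the WT clone both tags marked wild-type protein. The 21 samples comprised 14 HA or TY1 libraries, each with 1 peak list, and 7 control samples, for which no list was analysed here. R232fs, Y287X and G365R each had 2 HA and 2 TY1 lists, and WT had 1 of each.

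The deposited lists were narrowPeak tables, 1 per library and not pooled. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.2.9 and MACS2 2.2.7.1 were used and the genome build was hg19. The caller's settings and the control libraries it was given are not given in the sources used here. For each peak the deposited values were a fold enrichment (a linear ratio), a −log10 p-value and a −log10 q-value, a score, and the distance of the summit from the peak's start. The lowest −log10 q of the deposited lists ran from 1.30 to 1.32, close to the value of a q of 0.05. These fold and p values belong to the authors' peak calls. Within a list they served to rank, filter and describe peaks. Between lists they were compared mainly as ranks over one common set of regions. Counts of peaks past a fixed fold or −log10 q, centred log2 fold, and pileups and backgrounds solved from these values were also compared.

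Peaks on chromosomes 1 to 22 and X were used. Peaks on other sequences, 1.41% to 2.17% of a deposited list, were left out. No list of regions prone to mapping artefacts was applied here, so such regions may be among those counted and named. A window of 100 bp was set on each side of every summit, windows of all 14 lists that overlapped by 1 bp or more were merged into regions, and a list was counted as having a region when a summit of it fell there. This gave 190855 regions, of which 11291 (5.92%) were in all 14 lists and 80687 (42.3%) in a single list. Coordinates are hg19, counted from 1. No hg19 sequence or annotation was at hand, and the gene table supplied has another build, so regions are named by position, and motif, annotation and gene list results planned before the data were examined were left out.

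Library depth is not part of a peak list. Fold and −log10 p together fix the summit pileup and the local background under the caller's Poisson formula with a pseudocount of 1, and both were solved for each peak. In 12 lists at least 99.99% of the tested pileups lay within 0.05 of a whole number. In the WT TY1 list and the first G365R TY1 list only 6.73% and 8.06% did, so that these pileups had been scaled. The commonest background value of a list ran from 2.83 to 4.82 fragments per base and was used as the nearest measure of depth. In simulated peaks 100% of pileups were recovered.

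The numbers of peaks, covered length and median width were compared between tags by exact permutation of the labels within genotype (216 arrangements, 2-sided). Similarity of lists was the Jaccard index of regions, tested by exact permutation of tags within clones (128 arrangements), regrouping of clones (15) or re-pairing of lists (8), each 1-sided. At the 11291 shared regions the fold was ranked within each list and turned into normal scores, which were compared with limma 3.58.1 (moderated statistics with a trend, Benjamini-Hochberg adjustment over regions, threshold 0.05) in R 4.3.3. A change is in units of these scores, where 1 is 1 SD of a list's scores. The fit had 8 groups of genotype and tag and 6 residual degrees of freedom, and the lone WT lists were assumed to vary like the others. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

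HA and TY1 lists with the same replicate number came from the same clone, per the clone names given to the deposited lists, and their deviations from the group means correlated across regions with r = 0.792 in R232fs, 0.702 in Y287X and 0.503 in G365R. The numbers therefore pair the samples, which was decided before the calls of the fits were compared. The design fixed beforehand has no clone term, and a fit with clone as a term (3 residual degrees of freedom) is given beside it wherever it changes the count of calls, together with exact sign permutations of the clone differences (64 arrangements) for list summaries. Comparisons of TY1 lists between clones cannot hold clone as a term, and for them a fit with a random clone effect (estimated correlation of 0.735) is given beside the fit without it. In scores simulated for the 6-clone average, shifts of 0.5, 1 and 1.5 were recovered in 2%, 64% and 100% of 50 changed regions without the clone term and in 60%, 100% and 100% with it. For R232fs alone, shifts of 1.5 and 2 were recovered in 12% and 86% without the term and in 100% of regions with it. Shifts of 0.5 and 1 were recovered in 0% without the term and in 8% and 68% with it. With the term 10 unchanged regions were called in each simulation, and without it 0. For R232fs at a shift of 0.5 these 10 outnumbered the recovered regions (8% of 50). The fit with the term may therefore call more false regions than its threshold allows, above all where changes are small.

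Regions named in the text follow a rule fixed before the data were examined, namely up to 5 called regions with the largest change in each direction of each comparison, and the 5 HA-only and 5 TY1-only regions of each genotype with the highest median fold over the 2 lists that have them; only the clearest of them are printed. Alternatives were peaks of −log10 q of 10 or more, peaks of fold 5 or more, the 30563 strongest peaks of each list (equal length), whole peaks or windows of 250 bp, other similarity indices, ranks of −log10 p, centred log2 fold, regions in at least 10 lists, leaving out regions whose mean rank lay in the lowest 0.25, and each clone or list left out. Ranks of the recovered summit pileup, the clone term together with the other settings, and fits of only the R232fs and Y287X or only the G365R and WT lists were added after seeing the data.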

Results

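The series asked where RUNX1, a DNA-binding transcription factor of blood cell development, sits in Jurkat T-cell leukaemia cells when 1 product of the gene is mutant. R232fs and Y287X are truncating changes, a frameshift and a stop codon, and G365R replaces a single amino acid. Each mutant genotype had 2 clones, and each clone gave an HA list (mutant protein) and a TY1 list (wild-type protein of the same cells). A single WT clone, with wild-type protein under both tags, gave the measure of what the antibodies alone do. The 14 lists held 30563 to 86433 peaks on chromosomes 1 to 22 and X, with a median of 58259, and covered 13.8 to 46.6 Mb. Median peak width was 385 to 485 bp. The R232fs and Y287X lists differed from the G365R and WT lists in a way the labels do not explain. Highest summit pileups were 2904 to 17735 fragments in the former and 385 to 480 in the latter. The first peak of chromosome 1 started at 10007 to 10043 in the former and at 9871 to 9912 in the latter. The last ended at 249240614 or before in the former and at 249240644 or after in the latter. Whether the 2 sets were processed differently was not tested. A difference between these 2 sets of genotypes is therefore also a difference between 2 kinds of list.

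Mutant and wild-type RUNX1 gave lists of different length in the R232fs and G365R clones, and in opposite directions. In R232fs the mutant protein had 82062 ± 6182 peaks (SD, n = 2) and the wild-type protein 49626 ± 13455, a ratio of 1.68. In G365R the mutant protein had 30586 ± 33 peaks and the wild-type protein 59586 ± 3122, a ratio of 0.51. Y287X lists were of similar length (59743 ± 11103 and 65655 ± 22495, ratio 0.93), and the WT clone itself had 37472 HA and 59452 TY1 peaks, a ratio of 0.63. Averaged over the 6 mutant clones, HA and TY1 peak numbers did not differ past the threshold (fold 0.93, exact permutation of tags within genotype p = 0.694, longer HA list in 3 of 6 clones). In this average the opposite differences of R232fs and G365R offset each other. The R232fs and G365R ratios differed by 1.71 on the log2 scale, beside an SD between clones of 0.287 in R232fs and 0.0772 in G365R. An exact permutation of 4 clones allows no p below 0.333.

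**Figure D1:**
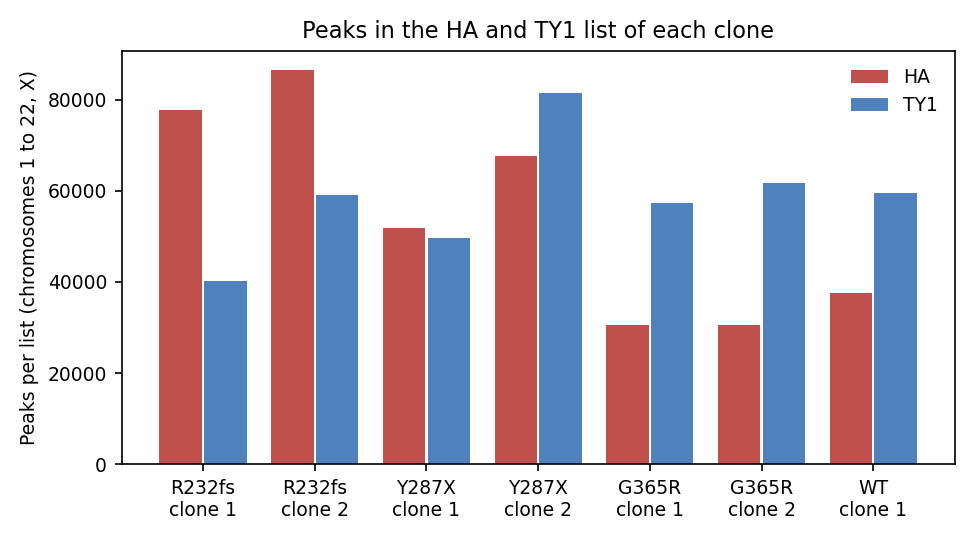
Peaks on chromosomes 1 to 22 and X (vertical axis) in the HA and TY1 list of each of the 7 clones (horizontal axis), 1 bar per list. HA bars exceed TY1 bars in both R232fs clones (77691 over 40112 and 86433 over 59140) and are below them in both G365R clones and in WT.

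Peaks of high enrichment followed another order. The mutant protein had fewer peaks of fold 5 or more than the wild-type protein in 6 of 6 clones (fold 0.717, exact permutation p = 0.037 within genotype and 0.0313 with clones paired), although in the first R232fs clone by only 18708 against 18715. Peaks of −log10 q of 10 or more did not pass the threshold (fold 0.728, exact p = 0.157 and 0.219 with clones paired, more HA peaks in 1 of 6 clones). For peaks of fold 5 or more with 1 clone left out, the exact permutation p was 0.0278 without either Y287X clone. It was 0.0556 and 0.0833 without the first and second R232fs clone and 0.111 without either G365R clone (fold 0.695 to 0.739). With clones paired it was 0.0625 each time, the smallest that 32 arrangements allow. The WT clone, with no mutant protein, had 11071 HA and 18721 TY1 peaks of fold 5 or more, a difference in the same direction from a single clone. HA peaks were also narrower, by a mean difference of -33.2 bp in median width (exact permutation p = 0.0185, HA wider in 1 of 6 clones), although with clones paired the exact p was 0.0625. In the WT clone the median widths were 390 bp for HA and 422 bp for TY1, a gap of similar size without a mutation. The commonest background value of a list, its nearest measure of depth, was higher in the longer of the 2 lists in 7 of 7 clones. In the first G365R clone and the WT clone, however, the TY1 pileups had been scaled and the 2 backgrounds are not like measures. In the other 5 clones it held too, although in the second Y287X clone by only 3.718 (TY1) against 3.702 (HA).

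Among lists as deposited, those of wild-type RUNX1 in G365R and WT cells were the most alike of all pairs. The TY1 lists of the G365R clones shared regions with the WT TY1 list at Jaccard indices of 0.627 and 0.622, and with each other at 0.610. The G365R HA lists reached 0.489 and 0.503 with the WT HA list, whereas the second R232fs HA list reached 0.197 with WT HA and 0.191 with the second G365R HA list, the lowest of the 91 pairs. HA and TY1 lists of the same clone shared 0.402 to 0.556. With lists of equal length that order changed, and the HA and TY1 lists of the second Y287X clone (0.742) and of the second R232fs clone (0.713) exceeded G365R TY1 with WT TY1 (0.692 and 0.6996). Lists of the same tag were more alike than lists of different tags by 0.0206 (0.405 against 0.384, exact permutation p = 0.141), which became 0.0214 with lists of equal length (exact p = 0.0156). Lists of the same genotype were more alike by 0.086 (exact p = 0.133, of 15 arrangements), and HA and TY1 lists of the same clone more alike than those of different clones of a genotype by 0.0736 (exact p = 0.125, the smallest that 8 arrangements allow).

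**Figure D2:**
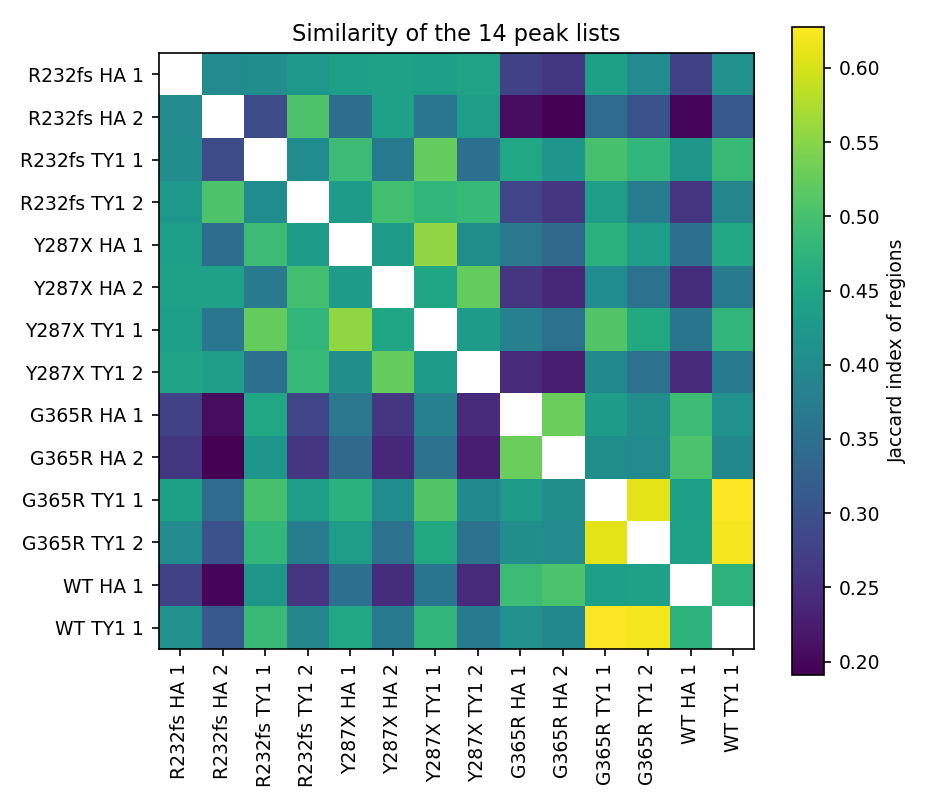
Jaccard index of regions (colour) for every pair of the 14 lists, named by genotype, tag and clone on both axes. The G365R TY1 and WT TY1 lists form the brightest block (0.610 to 0.627), and the second R232fs HA list against the G365R and WT HA lists the darkest (0.191 to 0.206).

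In lists as deposited, mutant-only regions were frequent in R232fs and rare in G365R, an order that turned with lists of equal length. In R232fs 7601 regions were in both HA lists and neither TY1 list and 516 in both TY1 lists and neither HA list, beside 25541 in all 4. In G365R the counts were 459 and 14985 beside 19767, and in Y287X 1295 and 2288 beside 29746. Splitting the same 4 lists by clone instead of tag gave 15406 regions in R232fs and 15522 in Y287X, more than the 8117 and 3583 of the tag split, but 2281 in G365R, fewer than its 15444. Most of the G365R contrast was present without a mutation, since 56.0% of its TY1-only regions were in the WT TY1 list and not in the WT HA list. The WT TY1 list held 79.6% of them and the WT HA list 25.3%. Of the R232fs HA-only regions 76.9% were in neither WT list, and of its TY1-only regions 37.2%. In Y287X the shares were 71.3% of HA-only and 59.3% of TY1-only regions, so that absence from WT was not particular to the mutant protein. These counts follow list length. With lists of equal length HA-only and TY1-only regions numbered 1204 and 794 in R232fs, 829 and 886 in Y287X, and 1791 and 2900 in G365R.

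**Figure D3:**
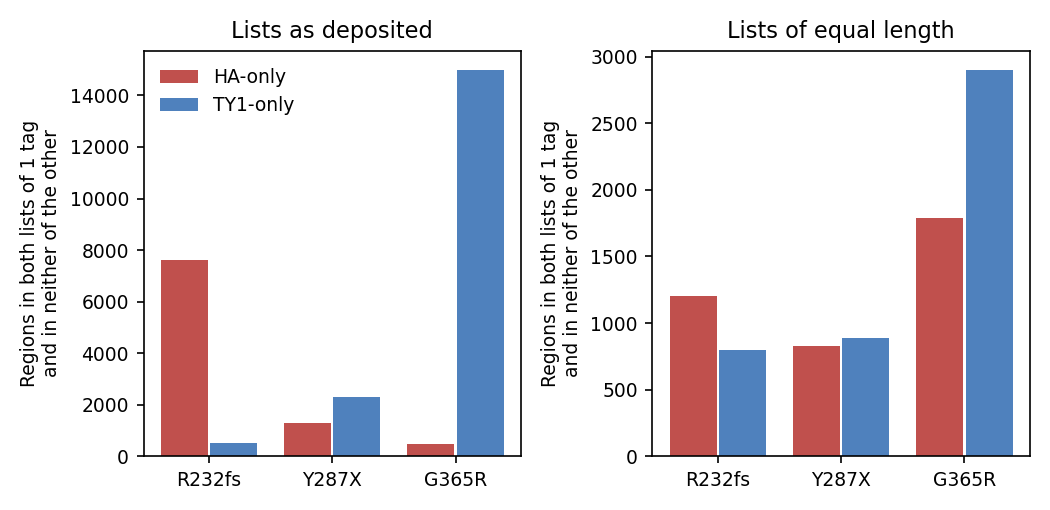
Regions in both lists of a tag and in neither list of the other tag (vertical axes, which differ between panels) for the 3 mutant genotypes, with lists as deposited on the left and of equal length on the right. HA-only regions of R232fs fall from 7601 to 1204, and TY1-only regions of G365R from 14985 to 2900.

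At the strongest of these regions mutant and wild-type summits lay side by side. In R232fs the HA-only region with the highest fold, on chromosome 8 at 61839092 to 61839376 (median fold 25.5), neighboured the TY1-only region at 61839921 to 61840236 (fold 31.6). The next HA-only region, on chromosome 1 at 160598789 to 160599045 (fold 23.6), neighboured the TY1-only region at 160599143 to 160599484 (fold 40.04). In Y287X the HA-only region on chromosome 10 at 90031255 to 90031484 (fold 14.6) was in all 4 R232fs and Y287X HA lists and in no TY1 list, and the neighbouring region at 90030631 to 90030985 (fold 21.3) was in all 7 TY1 lists and in 3 HA lists, all of G365R or WT clones. In G365R the HA-only region on chromosome 2 at 143886274 to 143886632 (fold 10.2) neighboured the TY1-only region at 143886749 to 143886987 (fold 18.4). Of the 5 strongest regions of each kind, some overlapped a whole peak of the other tag in at least 1 of its 2 lists. These were 4 R232fs HA-only, 5 R232fs TY1-only, 5 of each kind in Y287X, 5 G365R HA-only and 2 G365R TY1-only regions. Over all regions of each kind the shares were 8.2% (HA-only) and 50.4% (TY1-only) in R232fs, 28.4% and 15.6% in Y287X, and 73.6% and 1.2% in G365R. Of these 30 strongest regions 17 were still of 1 tag with windows of 250 bp and 4 with whole peaks merged. Of the pairs printed here only that on chromosome 8 was so with 250 bp windows, and none with whole peaks.

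Against the WT clone, the lists of truncated RUNX1 held many regions absent from the list of wild-type RUNX1 under the same tag. Of a clone's HA regions, 72.2% ± 6.1 (SD, n = 2) in R232fs and 62.3% ± 9.7 in Y287X were absent from the WT HA list, compared with 26.2% ± 1.0 in G365R. In both clones and not in WT there were 28224, 17310 and 2265 HA regions, while 10856, 12041 and 11152 WT HA regions were in neither clone. For the wild-type protein 31.3% ± 17.7, 41.1% ± 17.0 and 23.1% ± 2.3 of a clone's TY1 regions were absent from the WT TY1 list. There were 3523, 8364 and 4582 TY1 regions in both clones and not in WT, and 18519, 17061 and 8451 WT TY1 regions in neither clone. With lists of equal length the HA shares were 50.05%, 46.3% and 31.7% and the TY1 shares 32.7%, 31.7% and 18.0%. Absence from the WT HA list was also frequent without a mutation. In the WT clone itself 28302 of 59333 TY1 regions were not in its HA list, and 6354 of 37385 HA regions not in its TY1 list. With lists of equal length these were 8112 of 30563 and 8096 of 30547. The WT arm is a single clone and belongs to the same kind of list as G365R, so these shares carry no test.

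Relative binding of mutant and wild-type protein at the 11291 shared regions differed in R232fs cells when the 2 lists of each clone were paired. In that fit limma called 1169 regions higher and 1276 lower for the mutant protein in R232fs, 30 and 62 in Y287X, and 280 and 181 in G365R. In simulated scores the paired fit also called 10 unchanged regions, so that small counts in particular may hold false calls. On chromosome 10 the region at 101630058 to 101630381 was lower for the truncated protein by -2.01 ± 0.26 (SE, adjusted p = 0.00572) in R232fs and by -2.28 ± 0.26 (adjusted p = 0.0268) in Y287X, where its mean percentile within a list was 5.4 for HA and 62.0 for TY1. In G365R the region on chromosome 5 at 79947135 to 79947460 was higher for the mutant protein by 2.16 ± 0.18 (adjusted p = 0.00501), with mean percentiles of 34.9 for HA and 0.54 for TY1, and in the WT clone, with no mutation, they were 29.9 and 0.58. The fit without pairing, which was fixed beforehand, called 0 regions in each genotype with ranks of fold. At an unadjusted p under 0.05 limma counted 1368 in R232fs, 463 in Y287X and 590 in G365R, against 564.6 by chance. With ranks of summit pileup the fit without pairing called 317 in R232fs, 4 in Y287X and 745 in G365R. The paired calls fell to 31, 2 and 42 with regions of at least 10 lists, and leaving out single clones gave 374 to 2145 in R232fs (lowest without its second clone), 0 to 279 in Y287X (0 without either Y287X or either G365R clone) and 1 to 447 in G365R (2 and 1 without its own clones). In G365R the balance of directions also depended on the ranks, with 1017 higher and 1463 lower by −log10 p and 1411 and 1671 by summit pileup. In Y287X the paired calls rose to 704 by −log10 p and 923 by summit pileup.

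The regions altered for the truncated proteins of R232fs and Y287X overlapped. Of 62 regions lower for HA in Y287X by the paired fit, 52 were also called lower in R232fs (7.0 by chance for independent lists), and of 30 higher, 17 were (3.1 by chance), with 0 called in opposite directions. Between R232fs and G365R 43 regions were higher in both (29.0 by chance) and 72 higher in R232fs and lower in G365R (18.7 by chance). In turn 7 were lower in both (20.5 by chance) and 36 lower in R232fs and higher in G365R (31.6 by chance). All these calls come from 1 fit that uses the same spread of a region for every genotype. Calls of different genotypes are therefore not independent, and the counts by chance set no test. Across regions the HA minus TY1 scores correlated between any 2 of the 4 truncating clones with r = 0.442 to 0.603 and between any 2 of the G365R and WT clones with r = 0.476 to 0.491. Between the sets r lay between -0.115 and -0.0273. The mean within sets exceeded that between them by 0.568 (exact permutation p = 0.0286, 1-sided, the smallest that 35 splits of the clones allow). Regions are not independent replicates, and the clone is the unit of that test. Most of the 35 splits part clones of a genotype, which are themselves alike (r = 0.603 in R232fs, 0.463 in Y287X and 0.491 in G365R). Splits that keep genotypes whole are too few for a p under 0.05, so that the p does not by itself show that the sets differ. Between genotypes the mean r was 0.479 for R232fs with Y287X and 0.481 for G365R with WT.

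**Figure D4:**
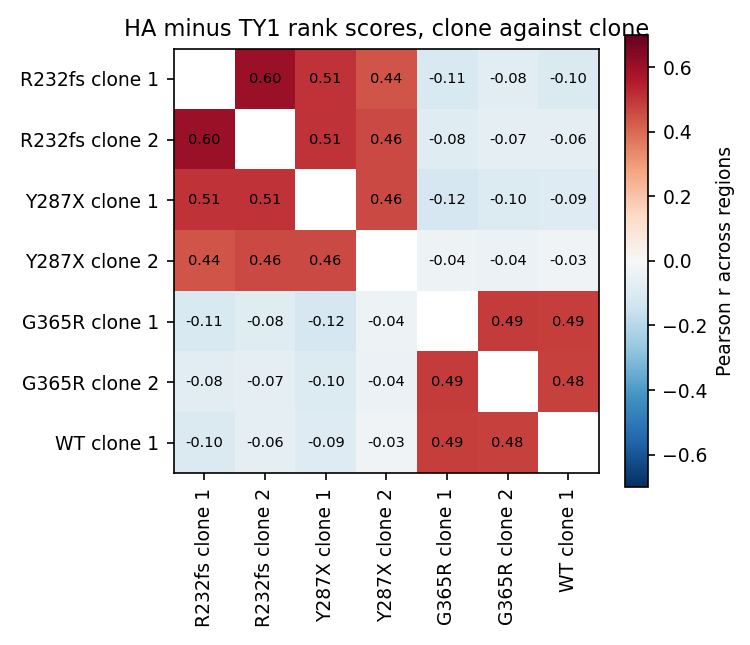
Pearson r across the 11291 shared regions between the HA minus TY1 score differences of each pair of the 7 clones (both axes). The 4 truncating clones form a block of 0.442 to 0.603, the G365R and WT clones a block of 0.476 to 0.491, and values between the blocks lie from -0.115 to -0.0273.

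Taking the WT clone's own HA minus TY1 difference into account left calls for truncated RUNX1 in the paired fit, against a WT arm of 1 clone. The clone term fits that clone exactly, so its spread was not measured and is assumed to be that of the other clones, and the kind of list differs as well. The paired counts also depend on the ranks. Ranks of −log10 p and of summit pileup raised them for R232fs and truncating minus WT. They also gave calls for Y287X and all 3 genotypes minus WT, where ranks of fold gave none. For R232fs minus WT 162 regions were higher and 184 lower, and for both truncating genotypes minus WT 125 and 107. The region on chromosome 11 at 108519022 to 108519297 was higher in the truncating clones than in WT by 2.09 ± 0.23 (adjusted p = 0.0276), with mean HA and TY1 percentiles of 88.9 and 71.7 in Y287X and of 33.3 and 81.1 in WT. In contrast, the region on chromosome 11 at 131481875 to 131482189 was lower by -2.46 ± 0.36 (adjusted p = 0.0311). For Y287X, G365R and all 3 genotypes minus WT limma called 0 regions in the paired fit, with 1982, 405 and 1486 at an unadjusted p under 0.05. Without pairing 0 were called with ranks of fold in each of the 5 comparisons with WT, with 614 (R232fs), 283 (Y287X), 45 (G365R), 518 (truncating) and 156 (all 3) at an unadjusted p under 0.05, but ranks of summit pileup gave 418 calls for R232fs, 64 for Y287X and 426 for truncating minus WT in the same fit. With regions of at least 10 lists the paired counts for R232fs and for truncating minus WT both became 0. All calls of both were also lost without either G365R clone or the first Y287X clone. Those for R232fs minus WT were lost without the second R232fs clone too.

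Among the comparisons of HA minus TY1 between genotypes, that of truncating with G365R clones, replicated on both sides, gave the most paired calls. In the paired fit 966 regions had a higher and 963 a lower HA minus TY1 difference in the truncating clones. On chromosome 3 at 149939105 to 149939362 the difference was 2.203 ± 0.180 higher in truncating clones (adjusted p = 0.00214), with a mean HA percentile of 60.6 in Y287X and 4.8 in G365R and TY1 percentiles of 32.7 and 38.2. On chromosome 5 at 79947135 to 79947460 it was lower by -2.01 ± 0.21 (adjusted p = 0.00343). Between R232fs and Y287X limma called 0 regions, with 1244 at an unadjusted p under 0.05. Without pairing limma called 0 for truncating minus G365R (1177 at an unadjusted p under 0.05) and 0 for R232fs minus Y287X (121). With ranks of −log10 p the unpaired fit called 282 for truncating minus G365R, and with ranks of summit pileup 1036. The paired count fell to 133 with regions of at least 10 lists, to 42 without the first G365R clone and to 200 without the second.

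Calls for the wild-type protein in truncating against WT cells depended on the ranks used. They rest on 1 WT TY1 list, whose spread is assumed to be that of the other groups, and coincide with the 2 kinds of list, so that they do not by themselves show another placing of the protein. With ranks of fold, TY1 scores of R232fs exceeded those of WT at 38 regions and were lower at 16, and those of Y287X were higher at 16 and lower at 4. The region on chromosome 2 at 11093894 to 11094212 was higher by 3.05 ± 0.18 in R232fs (adjusted p = 4.32e-05) and by 3.50 ± 0.18 in Y287X (adjusted p = 1.02e-05), at TY1 percentiles near the top of every truncating list and 66.3 in WT. Chromosome 1 had a region at 208362555 to 208362830 that was lower by -2.26 ± 0.38 in R232fs (adjusted p = 0.0399) and by -2.64 ± 0.38 in Y287X (adjusted p = 0.0237), with TY1 percentiles of 37.4, 24.3 and 97.3 in R232fs, Y287X and WT. G365R and WT differed at 0 regions by limma (334 at an unadjusted p under 0.05), and over all 3 genotypes 6 were higher and 0 lower. With a random clone effect the counts were 41 and 12 for R232fs, 19 and 5 for Y287X, 1 and 0 for G365R and 11 and 0 for all 3. Ranks of summit pileup raised the counts and turned the balance, to 233 higher and 351 lower for R232fs, 173 and 268 for Y287X and 10 and 32 for all 3, and ranks of −log10 p gave 778 and 615, 682 and 444, and 245 and 95. The largest change, on chromosome 13 at 113527353 to 113527628 (4.26 ± 0.27 in R232fs, adjusted p = 5.05e-05), vanished with ranks of summit pileup, where it was -0.0129. Leaving out the second R232fs TY1 list left 2 calls for R232fs and leaving out the first gave 648, and the second Y287X TY1 list left out gave 3 for Y287X.

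For the average over the 6 mutant clones limma called 825 regions higher and 903 lower for the mutant protein with pairing. Exchanging the tags of both G365R clones gave 2814 calls, so that chance cannot be excluded for the count. The same average minus WT called 0 regions with ranks of fold (1486 at an unadjusted p under 0.05). Ranks of −log10 p and of summit pileup did give calls for it. The region on chromosome 13 at 111037762 to 111038151 was higher for the mutant protein by 1.28 ± 0.11 (adjusted p = 0.00255), but HA also exceeded TY1 there in the WT clone, at percentiles of 49.4 and 23.8. The region on chromosome 10 at 101630058 to 101630381 was lower by -1.55 ± 0.15 (adjusted p = 0.00329), with 52.7 and 52.9 in WT. Without pairing limma called 0 regions, with 1120 at an unadjusted p under 0.05, and 14 with ranks of −log10 p and 368 with ranks of summit pileup. The paired count fell to 12 with regions of at least 10 lists, and with 1 clone left out it ran from 304 without the first G365R clone to 1457 without the first R232fs clone.

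The sets of lists also differed in where on the genome their regions lay. Chromosome 13 held 2.29% of the regions of an R232fs or Y287X list on average (2.09% to 2.47%) and 4.04% of a G365R or WT list (3.20% to 4.84%). The local background on chromosome 13, relative to that of other chromosomes, was 0.470 (0.434 to 0.5) and 0.850 (0.766 to 0.916), a ratio of 1.81. Chromosome 13 was singled out after all 23 chromosomes had been seen, so its separation was not tested. The shares of 6 others, chromosomes 3, 4, 7, 16, 17 and 20, also parted the 2 sets of lists without overlap. Their ratios, taken from log2 means over clones, were 0.829 to 1.17 against 1.75 for chromosome 13. Leaving chromosome 13 out changed the mean correlation of HA minus TY1 scores within sets to 0.494 and between sets to -0.0749.

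**Figure D5:**
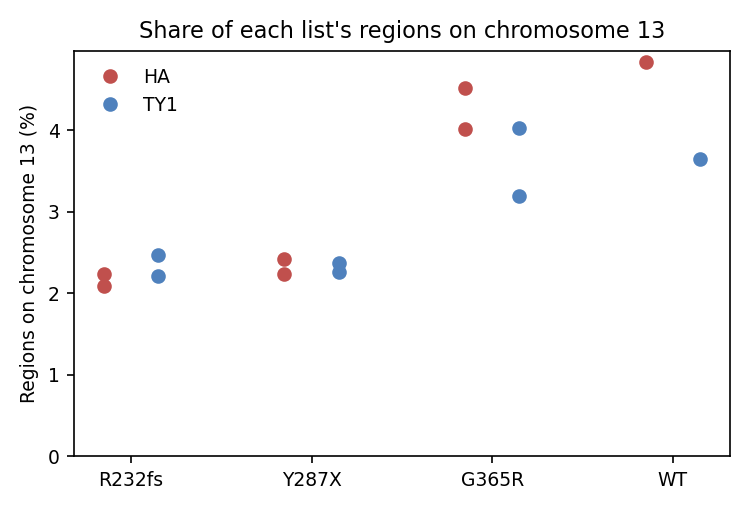
Percent of each list's regions that lie on chromosome 13 (vertical axis, from 0) by genotype (horizontal axis), 1 point per list coloured by tag. All 8 R232fs and Y287X lists lie between 2.09% and 2.47% and all 6 G365R and WT lists between 3.20% and 4.84%.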

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

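The tests of the antibodies, of the kind of list and of genotype in this part, and the test of depth without scaled lists, were chosen only after the results were seen, and the tests of depth over all clones, of the caller's background and of other groupings before.

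The ratio of HA to TY1 peak numbers went in opposite directions in R232fs and G365R clones, a difference of 1.71 on the log2 scale between the means (2 clones each). The smallest exact p of 4 clones is 0.333, so that the permutation could not test the difference. It was larger than the spread between the 2 clones of each genotype (SD 0.287 in R232fs and 0.0772 in G365R). This argues against differences between clones of a genotype as the only source, as far as 2 clones show their spread. The genotype of the clones cannot be told apart from depth or the kind of list. Antibody properties stay open. HA lists were longer than TY1 lists in R232fs (ratio 1.68) and shorter in the WT clone (0.63), as in G365R, but a single WT clone gives no spread to set the R232fs ratio against, and peaks of fold 5 or more were fewer for HA in R232fs as in WT (11071 against 18721). Depth is a candidate explanation. The permutations of clones below take them as exchangeable, although some share a genotype, so that their p-values may overstate the evidence. Over the 5 clones whose pileups had not been scaled the log2 ratio of peak numbers followed that of the commonest background value of each list (Pearson r = 0.980, exact permutation p = 0.00833, adjusted p = 0.0139 over 5 relations, Spearman rho = 1, exact p = 0.0167). Over all 7 clones, where the backgrounds of the first G365R clone and the WT clone are not like measures, r was 0.928 (exact permutation p = 0.000397, adjusted p = 0.00112, r = 0.996 without the 2 farthest clones, Spearman rho = 1, exact p = 0.000397), with the same sign in 7 of 7 clones. Over single lists, which are not independent within a clone, the relation of peak number to background was r = 0.914 in the 8 R232fs and Y287X lists (adjusted p = 0.00112, r = 0.856 without the 2 farthest). The values of 0.658 in the 6 G365R and WT lists (adjusted p = 0.148, -0.155 without the 2 farthest) and 0.362 over all 14 (adjusted p = 0.203) mix scaled with unscaled lists and decide nothing. The 2 sets hold 4 and 3 clones, too few for r within each.

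Calls of a difference between genotypes in HA minus TY1 came from tests of the difference itself. With clone as a term limma called 1929 shared regions for truncating minus G365R, 346 for R232fs minus WT, and 125 higher and 107 lower for truncating minus WT, where the fit without the term called 0 of each with ranks of fold (1177, 614 and 518 at an unadjusted p under 0.05) and 1036, 418 and 426 with ranks of summit pileup. With regions of at least 10 lists the paired counts became 133, 0 and 0. Both comparisons with WT rest on 1 WT clone, which the clone term fits exactly, and assume for it the spread of the other clones. Across regions these differences were alike among truncating clones and among G365R and WT clones, with a mean r of -0.0751 between the sets against 0.493 within them. The caller's local background is argued against, because ranks of the summit pileup, which leave it out, gave a difference of 0.663. What stays open includes the antibodies. The WT clone, with wild-type protein under both tags, shared its HA minus TY1 differences with the G365R clones (r = 0.476 and 0.486) and not with the truncating clones (r of -0.100 to -0.0273), which restates the pattern and does not decide whether the antibodies act differently in the 2 sets of lists. The kind of list stays open too. Every R232fs and Y287X list had a highest summit pileup of at least 2904 and every G365R and WT list of at most 480. The first peak of chromosome 1 started at 10007 or after in the former and at 9912 or before in the latter. No genotype had lists of both kinds, and a batch of libraries or of processing therefore cannot be told apart from truncation of RUNX1. The pattern may reflect either, and WT, which has no mutant protein, resembles G365R in it.

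The count of regions for the average of the 6 mutant clones was set against other groupings. Without a clone term the count was 0, which any split reaches (100 of 100 splits of the 12 lists), so that comparison is void and says nothing about chance. The highest other count was 1342, from a split between whole clones that set both Y287X clones and the first R232fs clone against both G365R clones and the second R232fs clone. That fit gives each genotype its own mean, so that the count reflects only the difference between the first and the second R232fs clone. The 2 other splits between whole clones that were drawn parted the clones of every mutant genotype and gave 0. With the clone term the count was 1728, and 2 of 32 patterns of exchanged tags gave as many, the real 1 included, so that chance cannot be excluded at 0.05. The other was 2814, from exchanging the tags in both G365R clones, which sets R232fs and Y287X against G365R with equal weight for each genotype and is not the contrast of the truncating mean with G365R, for which 1929 were called.

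A median of 1.84% of deposited peaks lay outside chromosomes 1 to 22 and X, in sequences that no comparison used (583 to 1602 peaks per list).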

How the results depend on the processing

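Ranks of summit pileup, fits of only 1 set of lists and the clone term joined to another setting were chosen after seeing the data, and the other settings before. The cause of the changes below was not tested, except that stricter or equal lists hold fewer peaks and that fits without a clone leave fewer lists. Peak lists carry no depth, and the WT arm is a single clone. The difference of mean correlations within and between the sets of clones stayed at 0.338 to 0.663 and at an exact p of 0.0286 in all 5 other settings. HA and TY1 lists of the same number are the same clone. Pairing them left the difference in median width at -33.2 bp with an exact p of 0.0625, and the count of fold 5 peaks past its threshold. The motif, annotation and gene list alternatives were not run.

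With peaks of fold 5 or more the log2 ratio of HA to TY1 peak numbers was -0.48 (exact p = 0.037). The width difference ran from -37.5 bp without the second Y287X clone to -28.8 bp without the first (exact p = 0.0278 and 0.0556). The excess similarity of lists of the same tag was 0.0409 with peaks of −log10 q of 10 or more (exact p = 0.0469), 0.0214 with lists of equal length and 0.0357 with fold 5 or more (exact p = 0.0156 each), and 0.0102 to 0.0344 with 1 clone left out (exact p = 0.313 without the second G365R and 0.0313 without the first R232fs clone). The genotype and clone differences kept their side of the threshold in every setting, where the designs allow no p under 0.05.

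With peaks of −log10 q of 10 or more, HA-only regions numbered 1493 in R232fs, 273 in Y287X and 88 in G365R and TY1-only regions numbered 1208 in Y287X. With lists of equal length, HA-only regions numbered 1204 in R232fs, 829 in Y287X and 1791 in G365R and TY1-only regions numbered 794 in R232fs, 886 in Y287X and 2900 in G365R. With peaks of fold 5 or more, HA-only regions numbered 764 in R232fs, 186 in Y287X and 67 in G365R and TY1-only regions numbered 820 in R232fs, 1240 in Y287X and 4796 in G365R. With whole peaks merged, TY1-only regions numbered 256 in R232fs and HA-only regions numbered 126 in G365R. With summit windows of 250 bp, TY1-only regions numbered 343 in R232fs and HA-only regions numbered 291 in G365R. With 1 clone left out, HA-only regions numbered 37532 to 43764 in R232fs, 15580 to 16327 in Y287X and 4011 to 4069 in G365R. With 1 clone left out, TY1-only regions numbered 6202 to 10247 in R232fs, 13444 to 30289 in Y287X and 30726 to 35187 in G365R.

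With peaks of −log10 q of 10 or more, HA regions of both clones absent from WT numbered 14167 in R232fs, 9406 in Y287X and 757 in G365R and WT HA regions absent from both clones numbered 4607 in R232fs, 5021 in Y287X and 4509 in G365R. With lists of equal length, HA regions of both clones absent from WT numbered 9538 in R232fs and 8571 in Y287X and WT HA regions absent from both clones numbered 6744 in G365R. With peaks of fold 5 or more, HA regions of both clones absent from WT numbered 6510 in R232fs, 4434 in Y287X and 918 in G365R and WT HA regions absent from both clones numbered 3477 in R232fs, 3603 in Y287X and 2300 in G365R. With peaks of −log10 q of 10 or more, WT TY1 regions absent from both clones numbered 8980 in R232fs, 9935 in Y287X and 3847 in G365R and TY1 regions of both clones absent from WT numbered 3889 in Y287X and 2493 in G365R. With lists of equal length, WT TY1 regions absent from both clones numbered 5885 in R232fs, 7307 in Y287X and 2949 in G365R and TY1 regions of both clones absent from WT numbered 5438 in Y287X and 2044 in G365R. With peaks of fold 5 or more, WT TY1 regions absent from both clones numbered 5410 in R232fs, 6714 in Y287X and 2205 in G365R and TY1 regions of both clones absent from WT numbered 4112 in Y287X and 2142 in G365R.

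For the fit without a clone term, with clone as a block, calls of HA minus TY1 numbered 2445 for R232fs, 92 for Y287X, 461 for G365R, 3 for WT, 346 for R232fs minus WT, 125 for truncating minus WT (higher), 107 for truncating minus WT (lower), 1929 for truncating minus G365R and 1728 for the 6-clone average. With ranks of −log10 p, calls of HA minus TY1 numbered 10 for R232fs, 47 for G365R, 282 for truncating minus G365R and 14 for the 6-clone average. With log2 fold centred on each list's median, calls of HA minus TY1 numbered 1 for R232fs. With regions of at least 10 lists, calls of HA minus TY1 numbered 17 for R232fs, 3 for Y287X, 8 for G365R, 2 for WT, 3 for truncating minus G365R and 5 for the 6-clone average. With ranks of summit pileup, calls of HA minus TY1 numbered 317 for R232fs, 4 for Y287X, 745 for G365R, 51 for WT, 418 for R232fs minus WT, 64 for Y287X minus WT, 320 for truncating minus WT (higher), 106 for truncating minus WT (lower), 1036 for truncating minus G365R and 368 for the 6-clone average. With 1 clone or list left out, the counts ran from 0 (without R232fs HA replicate 1) to 1 (without R232fs TY1 replicate 1) for R232fs.

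With ranks of −log10 p, calls of TY1 against WT TY1 numbered 1393 for R232fs minus WT, 1126 for Y287X minus WT and 340 for all 3 minus WT. With regions of at least 10 lists, calls of TY1 against WT TY1 numbered 205 for R232fs minus WT, 96 for Y287X minus WT, 9 for G365R minus WT and 90 for all 3 minus WT. With ranks of summit pileup, calls of TY1 against WT TY1 numbered 584 for R232fs minus WT, 441 for Y287X minus WT and 42 for all 3 minus WT. Without the lowest 0.25 of regions, calls of TY1 against WT TY1 numbered 34 for Y287X minus WT. With clone as a block, calls of TY1 against WT TY1 numbered 1 for G365R minus WT and 11 for all 3 minus WT. With only the G365R and WT lists, calls of TY1 against WT TY1 numbered 1 for G365R minus WT. With 1 clone or list left out, the counts ran from 2 (without R232fs TY1 replicate 2) to 648 (without R232fs TY1 replicate 1) for R232fs minus WT, 3 (without Y287X TY1 replicate 2) to 56 (without R232fs TY1 replicate 1) for Y287X minus WT and 3 (without Y287X TY1 replicate 1) to 14 (without R232fs TY1 replicate 1) for all 3 minus WT.

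In fits that keep the clone term, counts moved as follows. With regions of at least 10 lists, calls of HA minus TY1 numbered 31 for R232fs, 2 for Y287X, 42 for G365R, 0 for R232fs minus WT, 0 for truncating minus WT (higher), 0 for truncating minus WT (lower), 2 for all 3 minus WT, 133 for truncating minus G365R and 12 for the 6-clone average. With ranks of −log10 p, calls of HA minus TY1 numbered 704 for Y287X, 2480 for G365R, 772 for WT, 2010 for R232fs minus WT, 811 for Y287X minus WT, 1 for G365R minus WT, 1057 for truncating minus WT (higher), 746 for truncating minus WT (lower), 400 for all 3 minus WT and 3211 for truncating minus G365R. With log2 fold centred on each list's median, calls of HA minus TY1 numbered 356 for Y287X, 0 for WT, 782 for R232fs minus WT, 23 for Y287X minus WT, 258 for truncating minus WT (higher) and 281 for truncating minus WT (lower). Without the lowest 0.25 of regions, calls of HA minus TY1 numbered 221 for Y287X and 16 for Y287X minus WT. With ranks of summit pileup, calls of HA minus TY1 numbered 923 for Y287X, 3082 for G365R, 2267 for WT, 3123 for R232fs minus WT, 2287 for Y287X minus WT, 1660 for truncating minus WT (higher), 1501 for truncating minus WT (lower), 1640 for all 3 minus WT, 3821 for truncating minus G365R and 2966 for the 6-clone average. With only the R232fs and Y287X lists, calls of HA minus TY1 numbered 20 for Y287X. With only the G365R and WT lists, calls of HA minus TY1 numbered 851 for G365R. With 1 clone or list left out, the counts ran from 374 (without R232fs replicate 2) to 2145 (without Y287X replicate 1) for R232fs, 0 (without Y287X replicate 1) to 279 (without R232fs replicate 1) for Y287X, 1 (without G365R replicate 2) to 447 (without R232fs replicate 1) for G365R, 1 (without Y287X replicate 1) to 4 (without R232fs replicate 1) for WT, 0 (without R232fs replicate 2) to 204 (without R232fs replicate 1) for R232fs minus WT, 0 (without Y287X replicate 1) to 84 (without R232fs replicate 1) for truncating minus WT (higher), 0 (without Y287X replicate 1) to 76 (without R232fs replicate 1) for truncating minus WT (lower), 42 (without G365R replicate 1) to 1828 (without R232fs replicate 1) for truncating minus G365R and 304 (without G365R replicate 1) to 1457 (without R232fs replicate 1) for the 6-clone average.

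Of 24 region results named without the clone term and 73 with it, 9 changed sign under a setting. With ranks of summit pileup the chromosome 13 region at 113527353 became -0.0129, -0.314 and -0.0977 for TY1 of R232fs, Y287X and all 3 minus WT, and for all 3 the chromosome 1 region at 566187 became -0.172 and the chromosome 11 region at 32442474 became -0.267. With the clone term it gave 0.0323 for R232fs on chromosome 1 at 198799557 and -0.00369 for the average on chromosome 10 at 2940397. With regions of at least 10 lists and the clone term, chromosome 7 at 76256458 became -0.166 for R232fs and -0.208 for truncating minus WT. Of the 1243 values of named regions in other settings, 781 kept sign and side of the threshold and 453 kept only the sign.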

Other observations

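The counts of neighbouring summits in this part, the choice of chromosome 13 among 23 and the tests of its stretches corrected for level came only after the results were seen, and the other tests on chromosome 13 before.

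At a small number of sites the summits of truncated and wild-type RUNX1 lay beside each other in every truncating clone. In the 4 R232fs and Y287X clones 167 regions were in all HA lists and no TY1 list and 56 in all TY1 lists and no HA list, and 21 of the former lay within 1000 bp of one of the latter, at a median distance of 544 bp. Exchanging the tags in some of the clones gave at most 4 such pairs over the 7 other patterns, but these had only 2 to 18 regions in the smaller of their sets against 56. As a share of the smaller set the pairs were 37.5%, against 12.1% (7 of 58) over the other patterns together. Of these 4 had 0 pairs and the highest share was 33.3%, from a set of 3 regions. With 8 patterns no share of patterns under 0.05 can be had, and the difference was not tested. On chromosome 1 the HA region at 14075980 to 14076288 was in the 4 truncating HA lists and no other list, and the neighbouring region at 14075636 to 14075917 in all 7 TY1 lists and no HA list. On chromosome 5 the HA region at 75698805 to 75699037 was in the 4 truncating HA lists and no other, and the region at 75698284 to 75698544 in 7 TY1 lists and 3 HA lists. On chromosome 19 the HA region at 10253786 to 10254025 and the TY1 region at 10253434 to 10253699 were each in 4 lists, those of the truncating clones. Among the 3 G365R and WT clones 12 pairs were found between 137 HA and 8395 TY1 regions, and the 3 other patterns, with at most 264 regions in the larger set, give no like measure. The WT clone among them carries the wild-type protein under both tags, so that neighbouring summits also occur between the antibodies.

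Chromosome 13 held a larger share of regions in the G365R and WT lists (4.04%) than in the R232fs and Y287X lists (2.29%). Base composition of the libraries was not measured, and the background level of a chromosome stood in for it. A line was drawn through the other 22 chromosomes, of the change between the sets against the level in the R232fs and Y287X lists. The change of background on chromosome 13 lay 0.608 (log2) above that line, and the highest residual of the others was 0.105. This argues against a change that follows the level alone, and against base composition only as far as the level stands for it. An additional copy of the whole chromosome stays open. The ratio of relative background in 20 Mb stretches was 1.42 to 1.94 in 4 stretches and 1.08 from 100 to 120 Mb, and a ratio under 1.1, or a rise in a part only, had been set beforehand as values against it. The bound of 1.1 was wrong, because the ratio also falls with the level of a stretch. Against the line of the 143 stretches of other chromosomes, 100 to 120 Mb lay above by 0.246 (log2) in background, where the G365R and WT clones were not all higher than the others (exact permutation p = 0.143, 1-sided), and by 0.335 in summit pileup, where they were. The stretch from 60 to 80 Mb lay above by only 0.0585 and 0.0803. Of the 143 stretches 44 lay as high or higher in background and 27 in summit pileup, so that 60 to 80 Mb was within their range. The other 3 stretches lay above by 0.650, 0.576 and 0.513 in background, more than any of the 143 (highest 0.415), and by 0.396, 0.284 and 0.637 in summit pileup (highest of the 143, 0.336), so that the rise was unequal along the chromosome. Stretches of other chromosomes were as unequal in background, where the gap between the highest and the lowest was 0.592 on chromosome 13 and up to 0.676 elsewhere, but not in summit pileup (0.557 against at most 0.490). A whole copy therefore cannot be told apart from a gain or loss of part of the chromosome, which may also apply. No other biological explanation was tested, and the sets of lists differ in kind.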
